A study of Mus musculus with 12 samples.

How the data were processed

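RNA sequencing was done on liver tissue of 12 male C57BL/6 mice, 3 in each of 4 groups: wild-type and Otud3 knockout littermates, each with and without diethylnitrosamine (DEN), a liver carcinogen. Per the labels, DEN was given once by intraperitoneal injection at 25 mg/kg to mice 15 days old, and tissue was taken 30 weeks later. For mice without DEN, the sample labels used here give no age at collection and no sham injection. Age or injection may therefore differ along with DEN, and differences with DEN cannot be told apart from these. The labels do not say whether a piece of liver held tumour.

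The values are the authors' own. Per the file headers, each of 4 deposited tables (1 per group) gives, for each of its 3 libraries, a read count and a TPM (a length-scaled transcript share) for each gene. The authors' deposited read counts are expected counts, estimated per gene before deposit, as the values show: between 6.58% and 7.39% of the values per library are not whole. The deposited TPM values were used for Otud3 and to see which genes the tables list. Per the submitters' processing notes, HISAT2 2.2.1, Bowtie2 2.3.4.3, RSEM 1.3.1 and DESeq2 1.4.5 were used with the mouse build GRCm38.p6; their roles, the trimming and the strand setting are not given in the sources used here. Each table lists only protein-coding (mRNA) genes with a TPM of at least 0.01 in all 3 of its libraries, so a gene missing from a table is not a measured 0. Of 14944 genes in any table, 13371 are in all 4, and only these entered the tests. They hold at least 99.8% of the counts of each library. Gene identifiers matched the RefSeq GRCm38.p6 table for 14908 of the 14944 genes, and coordinates come from there. Without a stated strand setting, reads of overlapping genes cannot be told apart, and reads of near-identical genes (Cyp2a4 and Cyp2a5, Hspa1a and Hspa1b) can be split between copies.

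Total counts ranged from 29668861 to 31111765 per library, so depth differed little. No 2 libraries of a group agreed within sampling noise: chi-square per degree of freedom over genes ranged from 27.9 to 785.1, and all 12 were kept as separate samples.

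Counts were rounded to whole numbers and scaled by TMM. Genes were filtered with filterByExpr by group, which left 12909. One quasi-likelihood model (edgeR 4.0.16, glmQLFit and glmQLFTest, robust) was fitted to all 12 libraries with 1 coefficient per group and 8 residual degrees of freedom. Adjusted p is Benjamini-Hochberg over the genes tested, with 0.05 as the threshold. In the text, a gene "rose" or "fell" only if it passed this threshold. Log2 fold changes are given with standard errors, and CPM is the share of a library's counts after TMM scaling, per 1e+06 counts. The 5 contrasts set before the data were examined are DEN in wild type, DEN in labelled knockout, knockout label without DEN, knockout label with DEN, and their interaction. The mean DEN effect and the mean knockout effect over both strata were added after seeing the data.

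Gene lists (42, fixed before the data were examined) were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 40 lists with at least 3 tested members. The lists of mitochondrially encoded genes (0 measured) and pancreas markers (2 measured) were not tested. The same test with an estimated correlation, and fry, served as checks. Which lists are described in the text was chosen after their values were seen.

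The rule for named genes was set before the data were examined. It takes Otud3; the 5 largest changes in each direction among genes past the threshold with a mean CPM of at least 1 and non-overlapping libraries, skipping predicted gene models; the 3 genes with the smallest p where none passed; for each list described, up to 4 members with the smallest adjusted p; and a fixed set of marker genes. A few other genes are named, and are marked as chosen after their values were seen. Some genes that the rule names are not reported here.

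The steps were tested on simulated data for the DEN comparison in wild type, over 12846 genes. Of genes changed 2-fold, 32% were called; of genes changed 4-fold, 71%. Of unchanged genes, 0.0476% were called, and 0 genes were called in a simulated comparison with no change. Simulated genes vary independently, which real genes do not.

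Alternatives tried were DESeq2 1.42.0, limma-voom, RLE and library size scaling, other filters, a fold-change limit, only the groups compared, a replicate block, library sizes without the 20 most abundant genes and leaving out each library. Quality weights in limma-voom and setting genes missing from a table to 0 were added after seeing the data. Quality weights were run in 3 specifications, and the one that changes only the weights is reported. Alternatives written for files with only normalized values did not apply. Counts of calls were also compared with other splits of the same libraries.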

Results

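The data are RNA-seq profiles of liver from 12 mice in a 2-by-2 design: wild-type (WT) and Otud3 knockout mice, without DEN or 30 weeks after a single DEN injection, with 3 mice per group. Otud3 encodes a deubiquitinase. The series asks how loss of Otud3 changes gene expression in DEN-induced liver cancer. Libraries held 29668861 to 31111765 counts.

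Otud3 (Entrez 73162, chromosome 4, 138891063 to 138914026, GRCm38.p6) was read in every library. Its counts ranged from 201 to 409 in the 6 libraries labelled knockout and from 350 to 560 in the 6 wild-type libraries. Mean CPM was 13.25 ± 0.345 (SD, n = 3) in WT and 11.32 ± 4.17 in labelled knockout without DEN, and 14.94 ± 3.83 in WT and 11.07 ± 2.21 in labelled knockout with DEN. The log2 fold change was -0.23 ± 0.27 (SE) without DEN (edgeR adjusted p = 1) and -0.43 ± 0.27 with DEN (edgeR adjusted p = 0.581). In two-sided exact permutation tests of the knockout label within treatment (400 labellings, 3 measures), the difference was -0.563 in log2 TPM (p = 0.035, Benjamini-Hochberg adjusted 0.105), -0.356 in log2 CPM (p = 0.105, adjusted 0.158) and 0.10 in log2 relative transcript length, the count over the TPM (p = 0.685). None passed after adjustment. The length value was pulled down by 1 library: it was -0.863 in DEN labelled knockout replicate 1 and 0.0514 to 0.451 in the other 5 labelled-knockout libraries. In size the difference of 0.10 lay at percentile 99.39 of 9472 genes. Leaving out each library, tried after seeing the data, brought TPM (-0.71) and CPM (-0.491) past 0.05 without No DEN labelled knockout replicate 1 (exact permutation test, adjusted p = 0.0225 for both). Without DEN labelled knockout replicate 1, TPM (-0.652) and length (0.273) passed (exact permutation test, adjusted p = 0.015 for both), and without DEN labelled knockout replicate 2 the length difference was -0.0166. The labels do not say which part of the gene is deleted, so reads from a remaining part are possible, and gene-level counts do not check the genotype. The groups are therefore called labelled knockout.

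On principal components of log2 CPM, the first component (46.03% of the variance) set 1 library, DEN WT replicate 2, at 129.4, while the other 11 lay between -31.2 and 13.7. The second (18.65%) parted the other 5 DEN libraries, at 23.6 or more, from the 6 without DEN, at -8.88 or less. DEN WT replicate 2 lay at -26.87 on the second, within the range of the libraries without DEN. DEN WT replicate 2 held 56.5 CPM of Afp, the fetal liver gene alpha-fetoprotein (0.442 to 4.21 in the others), and 81.8 CPM of the collagen gene Col1a1 (2.02 to 7.04 in the others). It held 32.3 CPM of Glul, glutamine synthetase, against 721 to 1130, and 69.1 CPM of Cyp2e1 against 6330 to 9200. Its albumin transcript, Alb, was at 71000 CPM, within the 50500 to 90500 of the others. Alb and Cyp2e1 were named after their values were seen.

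**Figure D1:**
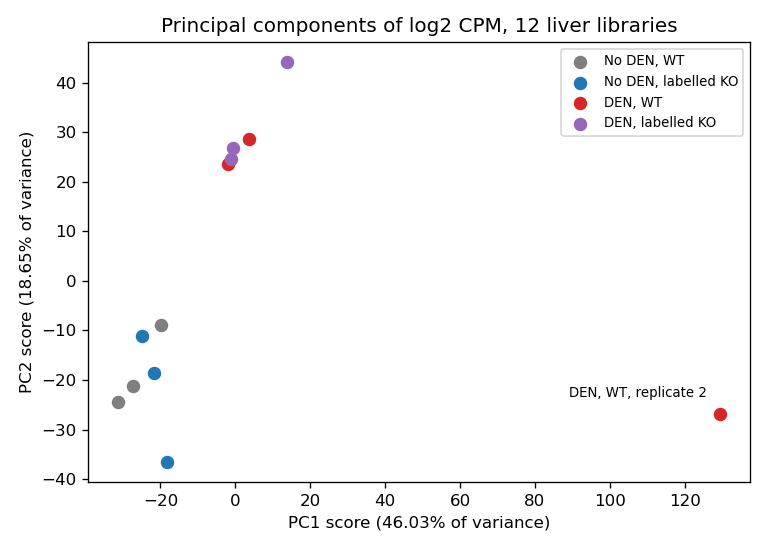
Scores of the 12 libraries on the first (x) and second (y) principal component of log2 CPM, 1 point per mouse, coloured by group. DEN WT replicate 2 lies alone at 129.4 on the first component.

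**Figure D2:**
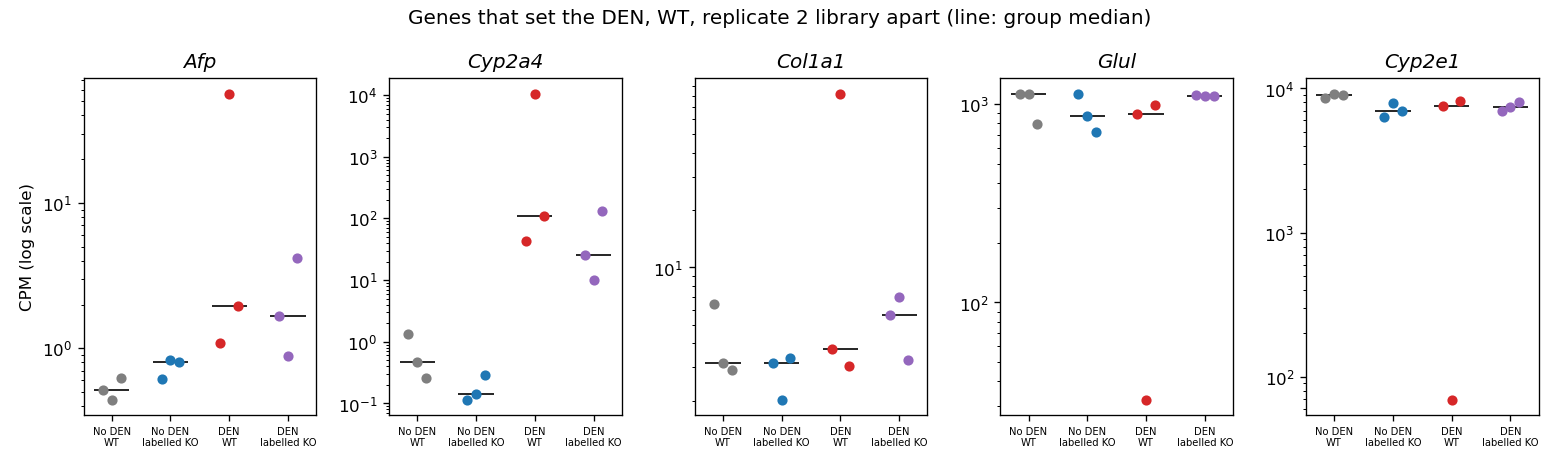
CPM (log axis) of 5 genes in each of the 12 libraries, by group, with a line at the group median; Cyp2e1 was chosen after its values were seen. DEN WT replicate 2 is the highest library for Afp at 56.5 and the lowest for Glul at 32.3 CPM.

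Livers 30 weeks after DEN differed from livers without DEN in 2131 genes when both genotypes were averaged: 1085 rose and 1046 fell (50.9% upward). With library size scaling in place of TMM the median of all genes shifted by 0.272 and 93.7% of the calls were upward, so directions are relative to the median gene. Genes of liver sinusoidal endothelial cells, which line the hepatic capillaries, were higher: 14 of 20 measured members rose, and 17 passed, all upward, when adjusted over the list alone. The list call was lost with an estimated correlation (camera adjusted p = 0.365), the only 1 of 17 alternatives to lose it. It held with fry. Kdr, the main VEGF receptor, rose by 1.60 ± 0.14 on the log2 scale (edgeR adjusted p = 0.000761), from 13.1 ± 2 to 34.2 ± 2.58 CPM in WT and from 8.63 ± 2.24 to 30.5 ± 4.62 in labelled knockout. Oit3 rose by 1.56 ± 0.15, Gpr182 by 1.29 ± 0.17 and Cdh5, which encodes VE-cadherin, by 1.62 ± 0.23. Each of these 4 was higher in all 6 DEN libraries than in all 6 others and stayed past the threshold in all 22 alternatives run for it. They were named for their small p in this comparison, in which 1268 of all 12909 genes (9.82%) had non-overlapping libraries. Their separation is therefore no further support.

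**Figure D3:**
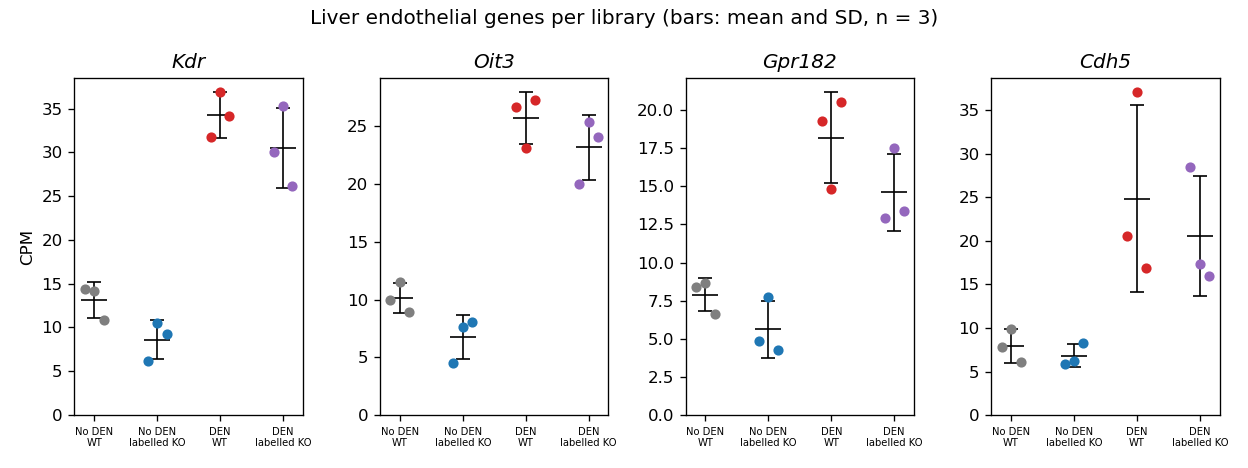
CPM of 4 liver endothelial genes in each library, by group, with group mean and SD (n = 3). Mean Kdr was 34.2 and 30.5 CPM in the DEN groups and 13.1 and 8.63 CPM without DEN.

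In 4 other lists some members rose with DEN, and each list's call was lost with an estimated correlation (adjusted p = 0.583 for each). Of lipogenic genes, 10 of 24 members rose (13 up and 1 down adjusted over the list alone), among them Srebf1, the transcription factor that drives fatty acid synthesis (1.31 ± 0.23), Fasn, fatty acid synthase (1.35 ± 0.30), Aacs (1.56 ± 0.27) and Acly (1.13 ± 0.25). Of matrix and TGF-beta genes, 8 of 30 rose (16 adjusted over the list alone), with Tgfb1 at 1.62 ± 0.23 and the proteoglycan gene Bgn at 0.80 ± 0.12. Col1a1, at 29.5 ± 45.3 CPM in DEN WT, rested on the library set apart above. Of Kupffer cell and macrophage genes, 6 of 19 rose (12 adjusted over the list alone), with Cd68 at 1.63 ± 0.33, Adgre1 at 3.05 ± 0.72 and Cd5l at 1.98 ± 0.50. DEN labelled knockout replicate 1 held 73.9 CPM of Adgre1, in a group at 29.2 ± 38.7, and 302 CPM of Cd5l, in a group at 137 ± 143. Without it Adgre1 was at 2 and Cd5l at 1.31, and Adgre1 was at 3.66 without No DEN WT replicate 2. Their calls were lost in 4 and 6 of 22 alternatives. Of liver cancer and oncofetal genes, 6 of 24 rose (10 adjusted over the list alone), with Akr1c18 at 4.05 ± 0.81 and Afp at 3.40 ± 0.93. Over all genes limma-voom called 0 of these 24 members and DESeq2 5, all higher. Akr1c18 was at 3.16 without DEN labelled knockout replicate 3 and Afp at 1.55 without DEN WT replicate 2, and the Afp call was lost in 13 of 22 alternatives.

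Acute phase and inflammation genes moved in both directions: 14 of 34 members fell and 4 rose (19 and 4 adjusted over the list alone). The list call was lost with an estimated correlation (adjusted p = 0.583). The fibrinogen genes Fgb and Fgg fell by 1.37 ± 0.25 and 1.47 ± 0.26 on the log2 scale, Socs3, an inhibitor of cytokine signalling, fell by 2.48 ± 0.41, and the adhesion gene Vcam1 rose by 1.65 ± 0.24. Saa1 fell by 5.33 ± 1.33 (edgeR adjusted p = 0.026), from a level without DEN that ranged widely, 323 ± 357 CPM in WT and 2880 ± 4780 in labelled knockout. It was at -3.03 without No DEN labelled knockout replicate 1 and -4.62, not past the threshold, without No DEN WT replicate 1. Of 19 circadian clock genes, 5 rose and 5 fell (7 and 5 adjusted over the list alone), and the list was not called (camera adjusted p = 0.138). Wee1 (2.35 ± 0.47, and 2.98 without No DEN labelled knockout replicate 2) and Per2 (1.24 ± 0.27) rose, while Nr1d1 fell by 0.908 ± 0.204 and Clock fell by 0.671 ± 0.152. The times of tissue collection are not given in the labels. Of hepatocyte identity genes, 3 of 26 fell (2 adjusted over the list alone), with the list call lost with an estimated correlation (adjusted p = 0.365). Among them were Nr5a2 (-0.56 ± 0.12) and the apolipoprotein gene Apoa1 (-0.62 ± 0.19), whose call was lost in 14 of 22 alternatives.

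The largest increases by the naming rule were in Cyp2a4 (10.3 ± 1.67) and Cyp2b9 (6.4 ± 1.22), cytochrome P450 genes, and in the endothelial gene Esm1 (4.9 ± 0.914), Gldn and Scd2. All 5 had their highest value in DEN WT replicate 2, where Cyp2a4 reached 10500 CPM against at most 130 elsewhere. Without it they were at 7.5, 4.43, 3.32, 2.55 and 2.09; Cyp2a4 was at 9.45 without DEN labelled knockout replicate 3 and Gldn at 5.57 without No DEN labelled knockout replicate 1. The calls of Cyp2a4, Cyp2b9, Esm1, Gldn and Scd2 were lost in 1, 2, 1, 9 and 5 of 22 alternatives. Reads of Cyp2a4 can be shared with its near-identical neighbour Cyp2a5. The largest decreases were in Saa1, Srrm4 (-2.76 ± 0.322), Acnat2, Socs3 and Fgl1, which was at -1.44 without No DEN labelled knockout replicate 1. The count of 2131 was 656 without No DEN WT replicate 3 and 3046 without DEN WT replicate 2. It also fell to 1004 without No DEN WT replicate 1, 1332 without No DEN labelled knockout replicate 2, and 893, 1056 and 1281 without DEN labelled knockout replicates 1, 2 and 3.

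In wild-type mice, 354 genes differed with DEN, 179 upward and 175 downward (50.6% upward, and 92.4% of the calls with library size scaling). Hspa1a, an inducible heat-shock protein gene whose reads can be split with Hspa1b, rose from 1.24 ± 0.788 to 29.3 ± 8.28 CPM. Its log2 fold change was 4.56 ± 0.454 (edgeR adjusted p = 0.0109), and 5.2 without No DEN WT replicate 1. Cyp2a4, Esm1, Bhlha15 and Abcc4 also rose, all with their highest CPM in DEN WT replicate 2; without it they were at 6.8, 3.02, 4.25 and 2.59. Without No DEN WT replicate 1 Cyp2a4 was at 13.2 and Bhlha15 at 7, both not past the threshold, and Cyp2a4 was at 12.9 without DEN WT replicate 1, again not past it, or replicate 3. Mrnip (-3.15 ± 0.617), Srrm4, Socs3, Tymp and Rab30 fell. The calls of Cyp2a4, Abcc4 and Rab30 were lost in 12 of 23 alternatives each, and those of Esm1 and Socs3 in 11 each. Bhlha15 lost its call in 10, Mrnip and Tymp in 9 each, Srrm4 in 5 and Hspa1a in 2. Of endothelial genes, 7 of 20 rose (13 adjusted over the list alone), including Kdr (1.38 ± 0.20) and Tie1 (1.24 ± 0.24). The calls of this list and of the unfolded protein response, proliferation and urea cycle lists were lost with an estimated correlation (adjusted p = 0.55 for each). The endothelial call held in the other alternatives run for it, fry among them. In the unfolded protein response list, 2 of 26 members rose, Dnajb9 (1.94 ± 0.35) and Sesn2 (1.20 ± 0.27), and the endoplasmic reticulum chaperone gene Hspa5 was at 1.37 ± 0.34 (edgeR adjusted p = 0.0542, and called in 7 of 23 alternatives). That list's call was also lost without DEN WT replicate 1 (camera adjusted p = 0.0523). The calls of Dnajb9 and Sesn2 were lost in 7 and 12 of 23 alternatives.

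Proliferation genes were higher in 28 of 30 members in wild-type mice with DEN, with a median log2 fold change of 1.39. One member, the cyclin gene Ccne2, passed the threshold (2.57 ± 0.41), and 17 did when adjusted over the list alone. Mki67, at 2.43 ± 2.32 CPM with DEN, did not pass (edgeR adjusted p = 0.069) but was called in 5 of 23 alternatives, DESeq2 among them. It was at 5.09 CPM in DEN WT replicate 2 and at most 1.44 in any other library, and without that library its log2 fold change was 0.998, with Aurkb at 1.32. The list call with the preset correlation stayed past the threshold without it (camera adjusted p = 0.000779). With all libraries and an estimated correlation the call was lost (camera adjusted p = 0.55). Of the urea cycle and amino acid list, Cth fell by 1.65 ± 0.36. The count of 354 depended on single libraries: it was 0 without No DEN WT replicate 3, 1038 without DEN WT replicate 3 and 443 without DEN WT replicate 2, and leaving out any library but the last moved it by over 1.5 times. It was also 0 when only the 6 wild-type libraries were fitted.

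In labelled-knockout mice, 25 genes differed with DEN, of which 19 rose and 6 fell (76% upward, and 95.8% of the calls with library size scaling). The endothelial genes Kdr (1.82 ± 0.20), Oit3 (1.78 ± 0.21) and Clec14a (1.93 ± 0.23) rose, each with edgeR adjusted p = 0.00811. Cnr2, which encodes a cannabinoid receptor (2.24 ± 0.299), Gatm (2.17 ± 0.231), a creatine synthesis gene, and Abcb1a (1.98 ± 0.309), a drug efflux pump gene, also rose. Gjc3 (-2.16 ± 0.331), Fkbp5 (-1.89 ± 0.293), Nedd4l, Thpo, which encodes thrombopoietin, and Josd2 fell. The Abcb1a call was lost in 13 of 23 alternatives, and those of Gjc3, Fkbp5 and Nedd4l in 12 each. Thpo lost its call in 8, Josd2 in 5, Cnr2 in 3, Clec14a in 2, and Kdr, Oit3 and Gatm in 1 each. All 34 measured ribosomal protein genes had negative values with a median of -0.364 (library size scaling moves the median of all genes here by 0.28). By edgeR and limma-voom 0 of them passed, by DESeq2 8 and with quality weights 22, all lower. The list call was lost with an estimated correlation (adjusted p = 0.503). The count of 25 was 912 without DEN WT replicate 2, which is not in this comparison but shares its estimate of the spread. It was 0 without DEN labelled knockout replicate 2, and it moved by over 1.5 times on leaving out any library except No DEN WT replicate 2 and No DEN labelled knockout replicates 2 and 3.

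The DEN effects of the 2 genotypes, which share no library, correlated across 12909 genes with r = 0.54 (genes are not independent replicates). Of the upward calls, 14 were in both lists, where 0.263 would be in both if the lists were independent, and of the downward calls, 3, against 0.0813. The lists are not independent, because both comparisons use the same estimate of each gene's spread. Genes with a low estimate tend to be called in both, so part of this excess is built in. The interaction, which tests the difference between the DEN effects, called 0 genes with edgeR (842 at an unadjusted p under 0.05, smallest adjusted p 0.735), 12 with DESeq2, 0 with limma-voom and 1 with library quality weights in limma-voom. The different counts of 354 and 25 are thus not shown to be different responses.

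With DEN, labelled-knockout and wild-type livers differed in 0 genes by edgeR (1308 at an unadjusted p under 0.05, smallest adjusted p 0.0837) and 0 by limma-voom, but in 140 by DESeq2 (34 higher, 106 lower) and in 513 by limma-voom with library quality weights (194 higher, 319 lower), an alternative chosen after seeing the data. Endoplasmic reticulum stress genes were lower in 25 of 26 members, with a median log2 fold change of -0.732. By edgeR, 0 passed over all genes and 17, all lower, when adjusted over the list alone. Over all genes limma-voom called 0 members, DESeq2 8 and limma-voom with quality weights 15, all lower. The list call was lost with an estimated correlation (camera adjusted p = 0.298), the only 1 of 17 alternatives to lose it. It held with fry. Hspa5 was at 654 ± 105 CPM in labelled knockout and 2130 ± 962 in WT (-1.70 ± 0.34, edgeR adjusted p = 0.216), Pdia4 at 136 ± 15.1 and 308 ± 54, Creld2 at 29.9 ± 7.6 and 132 ± 48.3 and Sdf2l1 at 19.1 ± 4.95 and 70 ± 13.3. DESeq2 and quality weights called each of these 4 genes (DESeq2 adjusted p = 0.000322 for Hspa5 and 3.51e-05 for Pdia4). In each of these 4 genes, every labelled-knockout library lay below every wild-type library with DEN. They were named for their small p in this comparison, and 2531 of all 12909 genes (19.6%) had non-overlapping libraries here. The separation is therefore no further support. The 3 genes with the smallest edgeR p, none past its threshold but each called by DESeq2, with quality weights and with missing genes set to 0, were Tbcel (0.85 ± 0.12), Tmed3 (-1.26 ± 0.18) and the heat-shock gene Hspa4l (-1.24 ± 0.18).

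**Figure D4:**
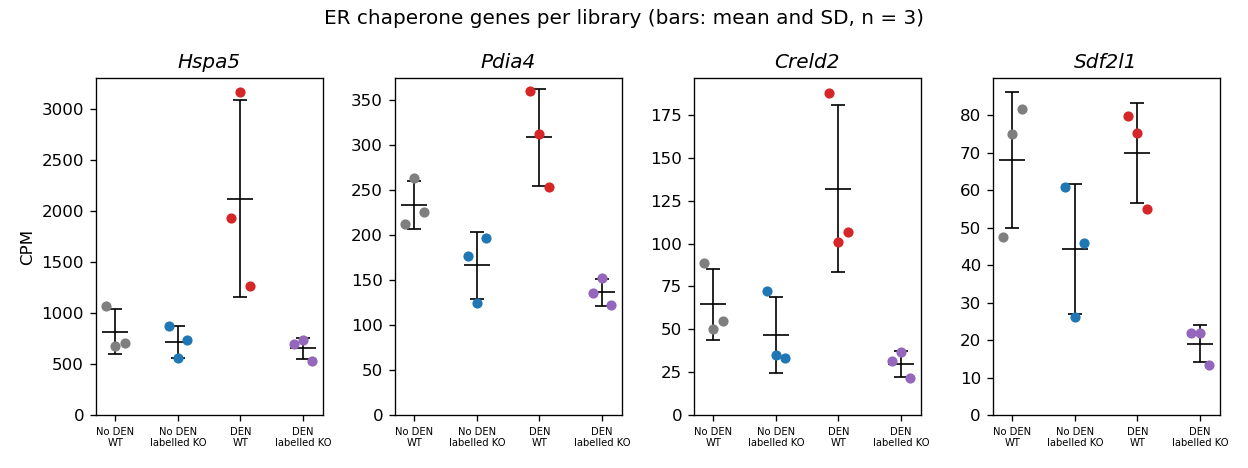
CPM of 4 endoplasmic reticulum chaperone genes in each library, by group, with group mean and SD (n = 3). With DEN, mean Hspa5 was 2130 CPM in wild type and 654 CPM in labelled knockout, a difference that did not pass over all genes by edgeR or limma-voom and passed by DESeq2 and with quality weights.

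Proliferation genes had negative values in 29 of 30 members of the same comparison (median -0.959) and genes of the pericentral, Wnt-dependent zone positive values in 20 of 22 (median 0.704), with 0 members of either list past the threshold by edgeR, limma-voom or DESeq2 and 1 of each with quality weights. Both list calls were lost with an estimated correlation (adjusted p = 0.945 for each) and without DEN WT replicate 2 (camera adjusted p = 0.274 and 0.093). DEN WT replicate 2 had the highest Mki67 and the lowest Glul of all libraries. B cell and plasma cell genes had positive values in 8 of 8 members, with the list call lost with an estimated correlation (adjusted p = 0.945), without DEN labelled knockout replicate 1 (camera adjusted p = 0.933) and without DEN WT replicates 1 and 3 (0.0587 and 0.101). The Cd79a value changed sign without DEN labelled knockout replicate 1, from 2.37 to -0.016.

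Without DEN, labelled-knockout and wild-type livers differed in 0 genes by edgeR (477 at an unadjusted p under 0.05, smallest adjusted p 1), 0 by limma-voom with or without library quality weights and 5 by DESeq2. Fatty acid oxidation and PPAR target genes had negative values in 35 of 37 members (median -0.601). The lipid droplet gene Plin2 was at 446 ± 69.2 CPM in labelled knockout and 884 ± 104 in WT, and Cidec at 3.83 ± 1.71 and 21.4 ± 12. Cholesterol synthesis genes had positive values in 26 of 26 members (median 0.721). Interferon response genes had negative values in 29 of 35 members. Of these 3 lists, 0 members passed over all genes by edgeR, limma-voom, DESeq2 or quality weights, or by edgeR adjusted over the list alone. Their list calls were lost with an estimated correlation (adjusted p = 0.472, 0.472 and 0.642), and the interferon call also without No DEN labelled knockout replicate 3 (camera adjusted p = 0.0764). Averaged over both treatments, the knockout label gave 0 calls with edgeR (869 at an unadjusted p under 0.05, smallest adjusted p 0.132), 0 with limma-voom, 47 with DESeq2 and 92 with library quality weights.

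The list test with the preset correlation called 18 of 40 lists for the averaged DEN effect, 19 for DEN in WT, 17 for DEN in labelled knockout, 13 for the knockout label without DEN, 13 with DEN and 16 for the interaction. None of these calls held with an estimated correlation, where the smallest adjusted p was 0.365, 0.55, 0.333, 0.472, 0.298 and 0.734 in the same order. Other splits of the same libraries called up to 24, 23, 17, 11, 21 and 24 lists. For the knockout label without DEN that is below the 13 called, but the 10 splits are too few for a share under 0.05. The lists are described here by their members.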

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

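All tests in this part were chosen after the results were seen, except the interaction test of the lists. With 3 mice per group, no test for an outlying sample was run on groups.

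By the interaction test with the preset correlation, the DEN effect differed between genotypes in 16 lists (camera adjusted p in parentheses). The DEN effect was more positive in labelled knockout for fatty acid oxidation and PPAR targets (1.05e-11), pericentral Wnt genes (6.3e-05), nuclear OXPHOS (0.000131), interferon response (0.000254), CYP drug metabolism (0.000528), urea cycle and amino acids (0.00157), bile acids (0.00175), stellate cells and fibroblasts (0.00612), periportal genes (0.00786), adipose and muscle markers (0.0234), liver endothelium (0.0365) and gluconeogenesis (0.0436). It was more negative for proliferation (1.72e-09), the unfolded protein response (1.27e-08), ribosomal proteins (1.09e-06) and cholesterol synthesis (2.04e-05). None held with an estimated correlation (smallest adjusted p = 0.734), and 30 of 60 splits of the libraries gave as many lists (highest other 24), so chance is not excluded for this count.

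Outside the genes tested, 185 genes were listed in both DEN tables and in neither table without DEN, against 29 the other way. Listing depends on the TPM floor of 0.01, and some of the 185 held few reads, down to a mean of 1.33 (Ksr2). With library size scaling the median of all genes was also 0.278 higher with DEN on the log2 scale. These genes are therefore not shown to be switched on. Reads of Cyp3a44, Slc7a11, Pnpla5, Tinag, Apln and Bex2, named after their values were seen, came mostly from DEN WT replicate 2 (3254.87 of Cyp3a44, and 4 or fewer in any other DEN library).

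DEN WT replicate 2 stands apart. A swap with a wild-type library without DEN, as the whole cause, is argued against by correlations of log2 CPM. This library correlated with the wild-type libraries without DEN at 0.8551 to 0.8635. Those correlated with each other at 0.9811 to 0.9868. A swap on top of another cause was not settled. Over the 25 genes called for DEN in labelled knockout, its score was level with the other DEN libraries. It lay 1.1 log2 units above the highest wild-type library without DEN. The estimate of the spread behind those calls includes DEN WT replicate 2, which favours genes in which it resembles its group mates, so the score cannot decide. On the second principal component this library lay at -26.87, among the libraries without DEN. A lower share of hepatocytes, as the whole cause, would raise the markers of all other cell types alike, but their list medians against its 2 group mates spread over 2.48 log2 units (SE 0.728; the extremes of 9 lists, whose genes are not independent). A few genes taking the counts is argued against by the share of its 20 most abundant genes, 27.9%, within the 24% to 31.4% of the others. A piece holding more tumour than the others may be the source, as may another difference in tissue sampling; neither was tested, because the labels do not describe the pieces.

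Unfolded protein response genes were lower in labelled-knockout than in wild-type livers with DEN. The lower values did not rest on DEN WT replicate 2 alone: without it the median of the 26 members was -0.656, with 23 lower. The SE of this median, 0.159, is over genes measured in the same mice, which are not independent. It does not measure the spread between mice. The list's median lay between -0.779 and -0.72 under 4 scalings, but none moved the median of all genes by 0.1 or more, so these do not test scaling. Genotype, scaling, time of collection and handling may each contribute and stay open. Over all genes 0 members passed by edgeR and limma-voom against 8 by DESeq2 and 15 with quality weights. The list call held with fry but was lost with an estimated correlation (camera adjusted p = 0.298). Otud3 counts do not check the label.

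Liver endothelial genes were higher with DEN. A lower hepatocyte share as the whole cause is argued against by the medians of 9 lists of cell types other than hepatocytes. They spread over 1.99 log2 units, from 1.73 for B and plasma cells to -0.268 for erythroid cells, with endothelium at 1.15. The SE of this spread, 0.385, is over genes, which are not independent, and does not measure the spread between mice. The list's median lay between 1.15 (SE 0.142) and 1.4 (SE 0.148) under the 4 scalings run. Library size scaling moved the median of all genes up by 0.272, and RLE moved it by -0.00347. Library sizes without the 20 most abundant genes moved it up by 0.233. None could have lowered the list's median by much, so these do not test scaling. More endothelial cells, or more transcript per cell, may underlie it, and these bulk libraries do not part them.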

How the results depend on the processing

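The averaged contrasts, quality weights, genes set to 0 when missing, and leaving out libraries outside a contrast, for gene lists or for the Otud3 permutation tests were chosen after seeing the data; the other alternatives were set before. Groups are given as DEN in WT, DEN in KO (labelled knockout), KO without DEN, KO with DEN, interaction, averaged DEN and averaged KO. Except where the construction shows it, the cause was not tested.

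Genes called were 354, 25, 0, 0, 0, 2131 and 0. DESeq2 called 1953, 882, 5, 140, 12, 3232 and 47. Quality weights, which gave DEN WT replicate 2 a weight of 0.073, called 4242, 2278, 0, 513, 1, 5514 and 92. Library size scaling called 1379, 337 and 3856 for the 3 DEN effects and 0 for the rest; library sizes without the 20 most abundant genes called 1317, 172 and 3280. A log2 limit of 1 left 185 for DEN in WT and 663 for averaged DEN. Fitting only the groups compared (4 residual degrees of freedom) called 0 for DEN in WT and 50 for DEN in KO. Setting missing genes to 0 called 566 for DEN in WT, 83 for DEN in KO, 2 for KO without DEN, 23 for KO with DEN, and 11 each for the interaction and averaged KO. limma-voom, RLE and the other filters stayed within 1.5 times. Leaving out 1 library gave 0 to 1038 for DEN in WT, 0 to 912 for DEN in KO and 656 to 3046 for averaged DEN, and 0 in every case for the KO contrasts and the interaction.

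Lists called by camera were 19, 17, 13, 13, 16, 18 and 17. With an estimated correlation 0 were called in each. fry called 6, 5, 0, 1, 0, 7 and 1, and its mixed test 15, 6, 0, 1, 0, 27 and 1. The list that fry called for KO with DEN was the unfolded protein response. Leaving out 1 library gave 15 to 23, 14 to 21, 9 to 18, 7 to 16, 13 to 18, 15 to 21 and 9 to 16.

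Replicate numbers do not pair the libraries: 4 of 18 same-number pairs had deviations correlated above 0.1 (range -0.19 to 0.22), and 4 of 12 libraries correlated best with their own number. A replicate block called 429, 18, 0, 0, 0, 1863 and 0 genes.

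Of the 82 called gene effects named, none changed sign in any alternative; 1436 of their values kept the call and 397 lost it. Of 32 called lists, 479 values kept the call and 65 lost it. Otud3, never called, changed sign for DEN in KO (main -0.0317) to 0.0163 with limma-voom, 0.258 with library size scaling, 0.205 without the 20 most abundant genes, 0.0111 with the replicate block and 0.125 with quality weights. Leaving out 1 library gave Otud3 values of -0.00994 to 0.361 for DEN in WT, -0.264 to 0.276 for DEN in KO, -0.537 to 0.00354 for KO without DEN, -0.434 to 0.106 for the interaction and -0.0468 to 0.223 for averaged DEN; for KO with DEN it gave -0.016 to 2.88 for Cd79a and -0.0145 to 2.85 for Fcmr. In the permutation tests it gave -0.71 to -0.443 for Otud3 TPM, -0.491 to -0.219 for CPM and -0.0166 to 0.273 for relative length. The Otud3 difference in CPM, labelled knockout minus WT, was -2.9, and -2.86 and -3.37 with RLE and library size scaling. Depth (29668861 to 31111765 counts) limits genes of few counts, which the tables leave out when under a TPM of 0.01 in any of a group's libraries.

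Other splits of the libraries gave at most 15 genes for averaged DEN (real 2131, 1 of 60 splits as large), a share under 0.05. That contrast was added after seeing the data, and the share is not adjusted for the other split comparisons. For the averaged KO effect and the interaction (0 real calls), 60 of 60 splits were as large (highest other 2 in both). With 3 against 3 there are 10 splits, too few for a share under 0.05: DEN in WT 354 (highest other 0, 1 split as large), DEN in KO 25 (0, 1), both KO contrasts 0 (0, 10). For KO with DEN, DESeq2 called 140 (highest other 12, 1 as large) and quality weights 513 (0, 1). For lists, 5, 2, 1 and 10 of 10 splits were as large in the 4 contrasts of 3 against 3 (highest other 23, 17, 11 and 21), and 28, 29 and 30 of 60 for averaged DEN, averaged KO and the interaction (24, 23 and 24), so chance is not excluded for those 3 list counts.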

Other observations

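Which lists are described here was chosen after their values were seen; the lists themselves and the naming rule were set before the data were examined.

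In further lists some members rose with DEN when both genotypes were averaged. Of the angiogenesis and hypoxia list, 7 of 20 members rose (9 adjusted over the list alone), among them Pecam1, an endothelial adhesion gene (1.35 ± 0.24), and P4ha1, a collagen prolyl hydroxylase gene (1.32 ± 0.19); neither lost its call in the 22 alternatives run for it. Kdr and Esm1 are also in this list. Of the monocyte and dendritic cell list, 4 of 12 rose (7 adjusted over the list alone), with Flt3 at 1.45 ± 0.36, Lyz2 at 1.52 ± 0.42 and Cd74 at 1.16 ± 0.33. The calls of Lyz2 and Cd74 were lost in 6 and 8 of 22 alternatives, and that of Flt3 in 4 of 21. The outlying library, DEN WT replicate 2, held 170 CPM of Cd74 (at most 78.7 elsewhere) and 1.08 CPM of Flt3 (at most 0.548 elsewhere), and the list's median there was 1.5 (SE 0.407) above its 2 group mates on the log2 scale. Without it Cd74 was at 0.802 and Flt3 at 1.1. Both list calls were lost with an estimated correlation (adjusted p = 0.583 for each). Of p53 target genes, Sesn2 (0.74 ± 0.19), Pmaip1 (2.40 ± 0.63) and Phlda3 (0.77 ± 0.21) rose and the death receptor gene Fas fell by 0.69 ± 0.17, with 4 of 25 members up and 1 down; the list itself was not called (camera adjusted p = 0.202). Pmaip1 was at 1.78 without DEN WT replicate 2 and 1.81, not past the threshold, without DEN labelled knockout replicate 1. The calls of Sesn2, Pmaip1, Phlda3 and Fas were lost in 5, 7, 7 and 3 of 22 alternatives.

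Of 13 measured genes listed before as reported partners of OTUD3, 0 differed between labelled knockout and WT with DEN over all genes by edgeR or limma-voom, and 1, Hspa5, by edgeR adjusted over the list alone and over all genes by DESeq2 and with quality weights. Trp53 was at -0.54 ± 0.25 (edgeR adjusted p = 0.496). The Trp53 value was -0.0719 without DEN WT replicate 2. Averaged over both treatments, the knockout label's smallest p values were for Wdfy1 (0.67 ± 0.09, edgeR adjusted p = 0.132), Stip1 (-0.65 ± 0.10, edgeR adjusted p = 0.216) and Zfp36l1 (-0.65 ± 0.10, edgeR adjusted p = 0.22), none past the edgeR threshold and all 3 called by DESeq2 and with quality weights. Wdfy1 was at 25.6 ± 2.31 and 17.6 ± 2.16 CPM in labelled knockout and WT without DEN, and at 22.8 ± 2.12 and 13 ± 0.542 with DEN (SD, n = 3). Without DEN the smallest were for Klf3 (0.59 ± 0.12), Cyp1b1 and Zfp36l1, and for the interaction Cad (-1.36 ± 0.26), Tbcel and Mogs; DESeq2 called Klf3, Zfp36l1 and the last 3, and edgeR none.

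Single libraries carried some values. Saa1 was at 8400 CPM in No DEN labelled knockout replicate 1, with 50.3 the lowest in its group. Cd79a was at 10.6 CPM in DEN labelled knockout replicate 1.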
